A study of Zea mays with 12 samples.

How the data were processed

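RNA of maize endosperm collected 16 days after pollination was profiled by RNA sequencing in 4 genotypes with 3 biological replicates each, 12 libraries in all. Per the labels' protocols, field-grown kernels were used, RNA was extracted with TRIzol and purified on RNeasy columns, ribosomal RNA was removed with Ribo-Zero, and paired reads of 125 nt were produced on a HiSeq 2500. Per the submitters' processing notes, FastQC, TopHat, Bowtie2 and Cufflinks were used with the genome build B73 RefGen_v3. Their versions, parameters and annotation are not given in the sources used here.

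The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled by mapped fragments) for 39448 gene models in 12 columns, 1 for each library, and column names that match the sample titles placed each library in its genotype. FPKM carries no read depth. In genes with FPKM of at most 0.5 the ratio of replicate 2 to replicate 3 lay within 0.02 (log2) of a small whole-number ratio in 13.2% to 33.5% of genes, so whole reads could not be recovered from the steps of the values and the depth of each library is unknown. No counting interval is given for that reason. FPKM is relative to the total of a library, so a gene's value also moves with the share taken by the most abundant transcripts. Reads of near-identical zein copies can be shared between gene models, and the level of a single zein model is uncertain.

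Some abundant models are listed at exactly 0 in single libraries: 35 models have both a 0 and a value of 20 or more, and 4 have both a 0 and a value of 1000 or more (z1A2_2, z1A1_3/z1A1_4, gz27 and z1C2, all zeins). A 0 can be a failed estimate, so such models are described as listed at 0, with the value of each library and no mean or fold.

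Gene names were taken from a reference table of the assembly Zm-B73-REFERENCE-NAM-5.0, which is another build than that of the values. It was used for names and for the order of neighbouring genes only. In it 18906 identifiers matched, 12425 of them among the tested genes, and 521 matched more than 1 reference gene. A name was found for 1752 tested genes. Symbols that fit more than 1 model are given with the identifier.

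FPKM values were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), after keeping the 17058 genes with FPKM of at least 1 in at least 3 libraries. A single model with 4 genotype means was fitted to all 12 libraries, with empirical Bayes moderation, a variance trend and robust estimation. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 6 contrasts were each single genotype and the double genotype against wild type, the double genotype against each single one, and the interaction, which is the departure of the double genotype from the sum of the single effects. Every adjusted p below is from limma or, for gene lists, from limma's camera, or, for windows of neighbouring genes, from a hypergeometric test. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds of FPKM are ratios of genotype means. Table handling used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

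The contrasts, the test, 21 gene lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The lists resolved to 334 members, counting a gene once in each list that holds it. Symbols fixed for the lists with no match in the reference table or the value table, such as those of several NAC and bZIP factors, were left out. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Camera compares the moderated t-statistics of a list, which weigh each change by its error, with those of all other tested genes. Its side is therefore not that of the median log2 fold change. Heat shock proteins in o2, for example, lay on the lower side with a median of 0.866, against 0.413 for all tested genes. The counts of members called over all genes are followed by those adjusted over the list alone where the numbers differ.

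Named genes are o2 and pbf1 in each comparison. For each comparison with wild type they include the 10 largest rises and the 10 largest falls among genes with a name, an adjusted p under 0.05, a mean FPKM of at least 10 in 1 of the genotypes and no overlap of the libraries. For the other comparisons the 5 largest each way were taken, without the overlap condition for the interaction. From each list the 2 to 4 most abundant called and not called members could be named, and up to 2 unnamed models each way. With 3 libraries against 3, chance gives no overlap in 10% of genes. The text names fewer genes than the rule gives.

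Replicates with the same number deviated together. The correlation of their deviations from the genotype means lay between 0.180 and 0.501 over 18 pairs of libraries from different genotypes, above 0.1 in all 18 of them, and in 31 of 36 comparisons a library correlated best with its own number. The main fit, fixed in advance, holds no replicate block, so its adjusted p and counts ignore this pairing. The fit with a replicate block was among the settings fixed in advance, and its values are given where they change a call. What the number marks, such as a block of plants or a day, is not given in the sources used here.

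The procedure was tested on simulated data with 200 changed genes among 17058 in a comparison built like that of o2 with wild type. It recovered 21% of genes changed by 0.5 on the log2 scale, 77.6% of those changed by 1 and 95.2% of those changed by 2. Of its calls, 5% were false. The changed genes were drawn from the more abundant tested genes, changes of 1 and 2 were falls only, and errors were independent between libraries. These shares therefore do not cover genes of low FPKM, rises of 1 or 2, or the shared deviations of replicates with the same number.

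The alternatives were pseudocounts of 0.1 and 5, no filter or a filter at FPKM 5, median-of-ratios scaling, scaling to the genes that are not zeins, a fit of the compared genotypes alone, a fit without trend and robust estimation, the replicate block, a required change of 2-fold, and leaving out each library in turn. Genes that are not zeins are all genes outside the zein list, so a zein model that the list misses is counted among them. Chosen after seeing the data were scaling to the genes outside the 100 most abundant, median-of-ratios scaling together with the block, leaving out all 4 replicate 1 libraries, and leaving out the 4 zein models listed at 0.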

Results

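Transcript levels were measured in maize endosperm, the storage tissue of the kernel, 16 days after pollination. The 4 genotypes were wild type (WT), the opaque2 mutant (o2), a line with an RNA interference construct against the prolamin-box binding factor gene (PbfRNAi), and the line with both lesions (PbfRNAi;o2, called the double genotype here), with 3 biological replicates each. O2 is a bZIP and PBF a Dof transcription factor, both known as activators of the zein genes, which encode the main storage proteins of maize endosperm. The comparisons ask which transcripts depend on each factor and on both together. FPKM sums over 39448 gene models ran from 430405 to 519817, and 14904 to 16413 models stood at FPKM 1 or more in a library. The read depth is unknown.

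The 10 most abundant genes held 39.0% to 41.5% of the FPKM sum in WT, 33.2% to 37.5% in PbfRNAi, 21.4% to 28.0% in o2 and 18.5% to 22.4% in the double genotype. The 26 models of the zein list held 25.7% to 33.3% in WT, 25.9% to 29.4% in PbfRNAi, 15.9% to 18.9% in o2 and 11.9% to 15.6% in the double genotype. Any zein model outside that list was not counted. Abundant models without a name were outside it whatever they encode. One of them, AF546187.1_FG007, stood at 5926, 14409 and 12045 in WT and at 20.5, 411 and 334 in the double genotype. These shares count as 0 the models listed at 0, which are z1A2_2, z1A1_3/z1A1_4 and z1C2 in WT replicate 2, the last 2 of these in WT replicate 3, and gz27 in all WT libraries and o2 replicate 1. In WT replicate 1 the first 3 stood at 22531, 11338 and 27678. Across genes, replicates 2 and 3 of a genotype correlated at r = 0.989 to 0.995, replicate 1 with either of them at 0.955 to 0.970, and libraries of different genotypes at 0.863 to 0.957. Genes are not independent replicates. In every genotype replicates 2 and 3 thus lay closer to each other than to replicate 1. Whether the 3 are equally independent is not given in the sources used here, and every SD, SE and p-value takes them as independent. Heat shock protein genes were higher in replicate 1 than in the mean of replicates 2 and 3, by a median log2 difference over 16 genes of 1.78 in WT, 1.34 in o2, 1.40 in PbfRNAi and 2.45 in the double genotype. Zein genes differed by −0.44, 0.76, −0.18 and −1.50 in the same order.

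**Figure D1:**
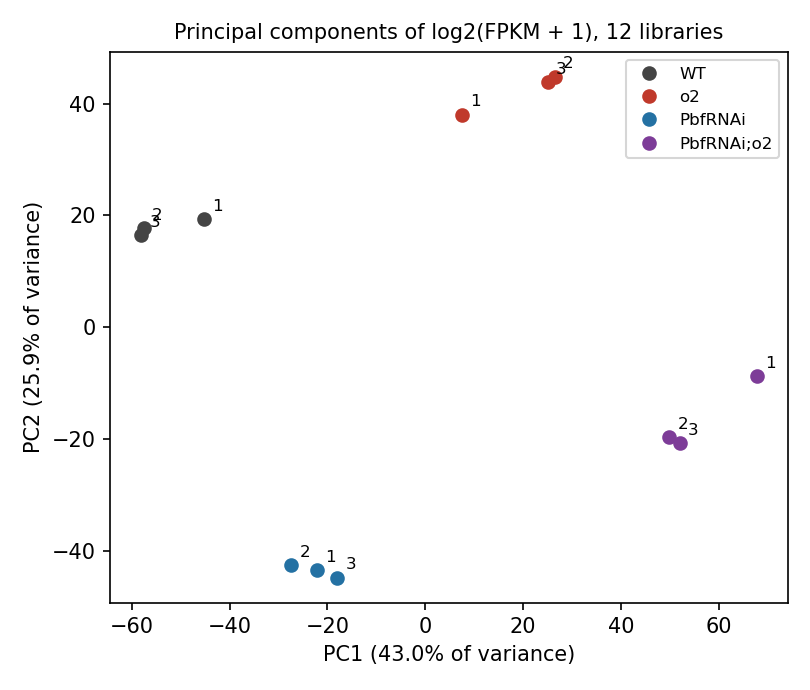
Scores of the 12 libraries on the first (43.0% of variance) and second (25.9%) principal component of log2(FPKM + 1), in arbitrary units. Each point is a library, coloured by genotype and marked with its replicate number, and the 4 genotypes form separate groups.

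The targeted genes were measured first. The o2 transcript (GRMZM2G015534) stood at FPKM 204 ± 22.01 (SD, n = 3) in WT, 0.467 ± 0.268 in o2, 119 ± 19.3 in PbfRNAi and 0.462 ± 0.297 in the double genotype. It fell in o2 (log2 fold change −7.14 ± 0.18, SE; limma adjusted p = 3.5e-10) and in PbfRNAi (−0.78 ± 0.18, adjusted p = 0.0087), the second call being lost with a pseudocount of 0.1 (adjusted p = 0.19). The pbf1 transcript (GRMZM2G146283) stood at 103 ± 6.41 in WT, 293 ± 45.9 in o2, 46.6 ± 9.09 in PbfRNAi and 59.5 ± 4.97 in the double genotype. It fell in PbfRNAi (−1.15 ± 0.15, adjusted p = 0.00017) and in the double genotype (−0.79 ± 0.15, adjusted p = 0.00086), and rose in o2 (1.48 ± 0.15, scaled 0.97, adjusted p = 4.8e-05). A second model with the name pbf1, GRMZM2G146267, stood at 12.6, 12.3 and 11.5 in the WT libraries and at 10.5, 13.9 and 11.7 in PbfRNAi.

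**Figure D2:**
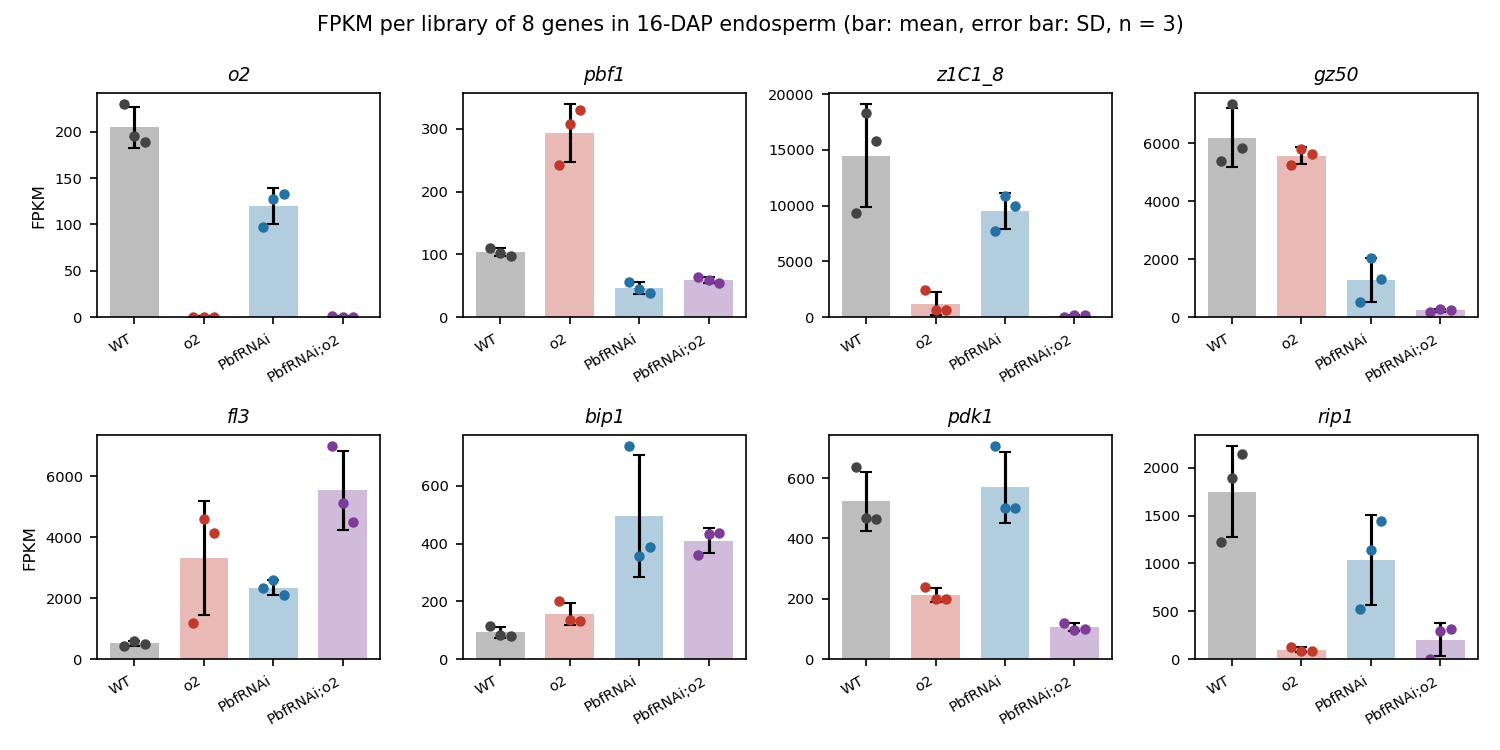
FPKM of 8 genes in the 4 genotypes, on linear axes that start at 0. Bars give the mean of 3 libraries, error bars the SD and points the single libraries, and the mean of pbf1 ranges from 46.6 in PbfRNAi to 293 in o2.

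FPKM is relative to the library total, and the value of the typical gene differed between genotypes. Median-of-ratios scaling removed a shift in the log2 fold change of 0.44 for o2 against WT, 0.18 for PbfRNAi against WT and 0.49 for the double genotype against WT. The shift was 0.06 for the double genotype against o2, 0.31 against PbfRNAi and −0.13 for the interaction. Changes below are on the FPKM scale, and counts and values called scaled are relative to this shift.

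**Figure D3:**
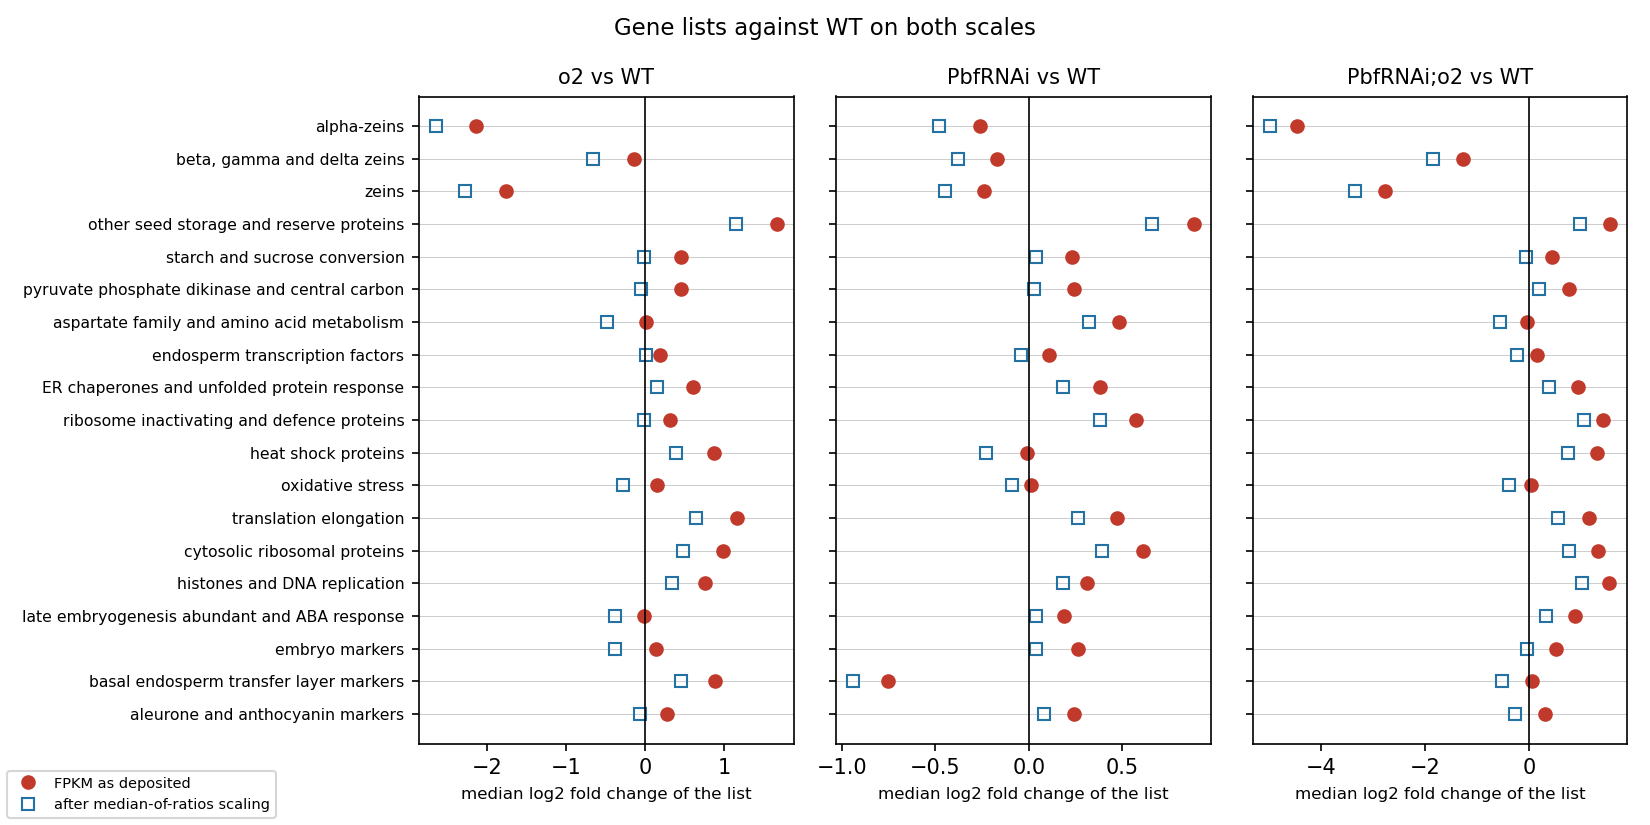
Median log2 fold change against WT of each gene list with at least 3 tested members, on the FPKM scale (circles) and after median-of-ratios scaling (squares). The 3 panels are o2, PbfRNAi and the double genotype, and the zein lists lie below 0 on both scales in each, with alpha-zeins at −2.14, −0.26 and −4.46 on the FPKM scale.

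Of 25 tested zein models 15 fell and 1 rose in o2, by 15 and 1 adjusted over the list alone, and 15 fell and 0 rose when scaled. The rise counted, also among the beta, gamma and delta zeins, is that of gz27, listed at 0 in WT. Models z1A2_2, z1A1_3/z1A1_4 and z1C2, listed at 0 in some WT libraries, counted as not called in each comparison with WT. Such zeros can be failed estimates. Among 20 alpha-zeins, 13 fell and none rose on either scale or adjusted over the list alone. In a split by subfamily made after the values were seen, those that fell were the 10 z1C1 models, to 0.182 of WT or less, and 3 of 9 z1A models, to 0.284 to 0.529 of WT. The abundant z1C1_8 went from 14478 ± 4615 to 1215 ± 1048 (log2 −3.85 ± 0.91, adjusted p = 0.0058), z1C1_7 from 4602 ± 1629 to 277 ± 173, and z1C1_12 from 1927 ± 793 to 1.52 ± 0.893. Without o2 replicate 1 the ratio of the o2 to the WT mean went from 0.0839 to 0.0421 for z1C1_8 and from 0.0602 to 0.0389 for z1C1_7. The beta-zein bz15 went from 18575 ± 6885 to 5926 ± 3269 (log2 −1.72 ± 0.33, adjusted p = 0.0015), and the delta-zein dzs18 from 36.8 ± 23.9 to 0.488 ± 0.334, a ratio of means of 0.0133, which became 0.0212 without WT replicate 1 and 0.00824 without o2 replicate 3. The gamma-zeins gz16 (24282 ± 2808 in WT, 26902 ± 5129 in o2; adjusted p = 0.63) and gz50 (6194 ± 1024 and 5571 ± 286, adjusted p = 0.77) did not pass. The gamma-zein gz27 was listed at 0 in the WT libraries and at 0, 22675 and 23594 in o2. Of the 5 beta, gamma and delta zeins, 2 fell and 1 rose (2 and 0 when scaled).

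By camera the zeins lay below other genes in o2 (adjusted p = 4.19e-30; adjusted p = 0.0161 with an estimated correlation), as did the alpha-zeins (1.18e-29; adjusted p = 0.0178 with an estimated correlation) and the other zeins (0.000519; adjusted p = 0.0292 with an estimated correlation). When scaled, the adjusted p with an estimated correlation was 0.203 for the zeins, and the preset one for beta, gamma and delta zeins was 0.083. Their mean change was 0.69 and their median −0.14, a difference of sign that rests on gz27. The legumin gene leg1 rose 3.18-fold (1828 ± 70.1 to 5817 ± 243; log2 1.67 ± 0.15, scaled 1.15, adjusted p = 2.3e-05). All 3 tested genes of other reserve proteins rose on the FPKM scale, and 1 when scaled (camera adjusted p = 0.19).

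Most genes of protein synthesis rose in o2, with rises beyond the shift among them. Of 29 cytosolic ribosomal protein genes 25 rose (25 adjusted over the list alone, 15 scaled) and none fell, and camera placed them above other genes (adjusted p = 1.17e-05; adjusted p = 0.346 with an estimated correlation). All 4 translation elongation genes rose, 3 of them when scaled, among them EF1-A (370.2 ± 14.5 to 777 ± 96.2) and elfa3 (105 ± 6.02 to 275 ± 18.97). Camera gave them an adjusted p = 0.0218 (adjusted p = 0.331 with an estimated correlation), and 0.0683 with the replicate block and 0.0594 without WT replicate 1 did not pass.

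Chaperone, starch and carbon genes in o2 moved largely with the shift. Endoplasmic reticulum (ER) chaperone genes were higher in 14 of 22 cases and lower in none (15 and 0 adjusted over the list alone), and when scaled 4 were higher and 2 lower. The protein disulfide isomerase gene PDIL1-1 went from 386 ± 79.7 to 854 ± 88.8 (scaled log2 0.64; adjusted p = 0.043, and 0.053 scaled to genes outside the 100 most abundant). Starch and sucrose genes were higher in 11 of 23 cases and lower in none, the same adjusted over the list alone, but 1 higher and 3 lower when scaled. The ADP-glucose pyrophosphorylase genes sh2 (1542 ± 245 to 3495 ± 1089.9) and bt2 (803 ± 139 to 2164 ± 855) passed on the FPKM scale but not when scaled (adjusted p = 0.1 and 0.088). The starch branching enzyme gene ae1 rose on both (601 ± 73.9 to 1598 ± 503; scaled log2 0.84, adjusted p = 0.032). Pyruvate phosphate dikinase gene pdk1 fell to 0.406 of WT (523 ± 98.04 to 212 ± 21.8; log2 −1.29 ± 0.17, adjusted p = 0.0002). The other such gene, ppdk2, was more abundant and had no like fall. It stood at 1313, 1352 and 1300 in WT, 1025, 1540 and 1518 in o2 and 798, 1375 and 1361 in the double genotype. The central carbon list that holds both genes had 8 genes higher and 1 lower of 15 (10 and 1 adjusted over the list alone, 3 and 1 scaled).

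Outside these groups the largest rises in o2 among named genes were those of BURP9 (0.119 ± 0.0910 to 44.9 ± 17.3) and BURP6 (3.19 ± 0.247 to 136 ± 77.8), whose products carry a BURP domain. The pathogenesis-related gene pr10 rose 19.8-fold and the proteinase inhibitor gene psei10 went from 27.5 ± 17.9 to 304 ± 80.5, 11-fold, and 17.6-fold without WT replicate 1. The gene ZIP4, of a family of zinc transporters, rose 12.8-fold. The regulator gene fl3 rose 6.35-fold (522 ± 85.00 to 3317 ± 1863) and sdh1, for sorbitol dehydrogenase, 4.63-fold. Within the central carbon list above, the glycolytic genes gpc4 and gpc3 rose 3.77-fold and 3.61-fold, which became 6.15-fold and 6.08-fold without WT replicate 1. The ribosome-inactivating protein gene rip1 fell from 1749.5 ± 476 to 99.8 ± 26.03 (log2 −4.11 ± 1.33, adjusted p = 0.028), a call lost without WT replicate 2 (adjusted p = 0.073), WT replicate 3 (0.08), o2 replicate 2 (0.075) or o2 replicate 3 (0.075). In its list of defence genes 6 rose and 1 fell of 18 (5 and 1 adjusted over the list alone, 3 and 2 scaled).

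Amino acid genes of the aspartate family lay below other genes in o2 by camera (adjusted p = 0.000134; adjusted p = 0.0358 with an estimated correlation), with 1 higher and 2 lower of 11 (0 and 2 adjusted over the list alone, 0 and 3 scaled). In it lkrsdh1, which encodes a lysine-degrading enzyme, stood at 114 ± 16.6 in WT and 44.8 ± 17.9 in o2 (adjusted p = 0.1, and 0.00044 without PbfRNAi;o2 replicate 1, which shares the estimate of spread). Oxidative stress genes rose in 4 and fell in 4 of 22 cases (4 and 3 adjusted over the list alone, but 1 and 5 scaled; camera adjusted p = 0.000766; adjusted p = 0.161 with an estimated correlation), and the superoxide dismutase gene sod4 fell to 0.367 of WT. Endosperm transcription factors rose in 6 and fell in 3 of 14 cases (7 and 3 adjusted over the list alone, but 2 and 5 scaled; camera adjusted p = 0.0149; adjusted p = 0.0698 with an estimated correlation). With median-of-ratios scaling they did not pass camera (adjusted p = 0.256).

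The other lists had few scaled calls in o2. Heat shock proteins were higher in 5 of 16 cases (0 scaled), histone and replication genes in 6 of 18 (4 adjusted over the list alone, 1 scaled), and basal endosperm transfer layer markers in 3 of 9 (0 scaled, and 0 adjusted over the list alone). Late embryogenesis genes were higher in 1 of 5 cases, embryo markers in 1 of 4, and aleurone markers higher in 2 and lower in 1 of 5 (2 and 2 adjusted over the list alone), against 1, 2 and 2 lower and none higher when scaled. The 2 embryo surrounding region markers and the 1 green tissue marker were not called. Late embryogenesis genes passed camera without WT replicate 1 (adjusted p = 0.0204, against 0.0608; adjusted p = 0.266 with an estimated correlation). In total 8282 genes were higher and 448 lower in o2 of 17058 tested. Scaled, 1510 were higher and 1355 lower. Scaling to genes that are not zeins gave 2551 and 902, and scaling to genes outside the 100 most abundant turned the balance, with 1124 and 1820.

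In PbfRNAi single zein models changed in both directions. Of 25 models 6 fell and 2 rose, on both scales and adjusted over the list alone. The rises counted are those of z1A2_1 and of gz27, whose WT values of 0 can be failed estimates. The gamma-zein gz50 fell to 0.208 of WT (6194 ± 1024 to 1290.3 ± 766; log2 −2.46 ± 0.38, adjusted p = 0.00066), and z1C1_12 went from 1927 ± 793 to 5.48 ± 0.196. The alpha-zein z1A2_1 rose from 1038 ± 256 to 22835 ± 611 (log2 4.49 ± 0.41, adjusted p = 1e-05), and gz27, listed at 0 in WT, stood at 6134, 7229 and 6699. Values of z1C1_8 (14478 ± 4615 and 9486 ± 1601, adjusted p = 0.71), bz15 (18575 ± 6885 and 15902 ± 1455, adjusted p = 0.76) and gz16 (24282 ± 2808 and 20796 ± 4279, adjusted p = 0.5) did not pass, although that of z1C1_8 did without the 4 replicate 1 libraries (0.00051). Camera placed zeins below other genes (adjusted p = 0.0019; adjusted p = 0.67 with an estimated correlation), but not with median-of-ratios scaling (adjusted p = 0.125). The 20 alpha-zeins, with 5 falls and 1 rise, had an adjusted p = 0.00219 (adjusted p = 0.67 with an estimated correlation), and the beta, gamma and delta zeins held 1 rise and 1 fall of 5. The median zein change was −0.24 and the mean 0.71, a difference of sign to which z1A2_1 and gz27 contribute.

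Of 22 ER chaperone genes 10 rose in PbfRNAi and 3 fell (12 and 3 adjusted over the list alone, 8 and 3 scaled). The chaperone genes bip1 (92.96 ± 19.6 to 494 ± 211; log2 2.34 ± 0.26, adjusted p = 4.6e-05) and bip2 (16.98 ± 0.828 to 167 ± 70.9) rose, as did PDIL1-1 (2.91-fold), PDIL1-2 (7.82-fold) and PDIL2-3 (3.86-fold), which encode protein disulfide isomerases. The 3 that fell, named after their values were seen, encode protein disulfide isomerases too. They were PDIL5-1 (GRMZM2G443655, 26.5 ± 1.85 to 0.430 ± 0.158, adjusted p = 0.0339; the double libraries stood at 61.5, 0.406 and 0.148) and the PDIL1-4 models GRMZM2G033829 (mean 5.67 to 0.617; log2 −2.04 ± 0.18, adjusted p = 6.15e-06) and GRMZM2G034143 (mean 14.6 to 7.72; log2 −0.84 ± 0.12, adjusted p = 0.00031). The call of PDIL5-1 was lost, at 0.053 to 0.094, without any 1 of the WT or PbfRNAi libraries or o2 replicate 3. The list missed the threshold by camera (adjusted p = 0.0938; adjusted p = 0.822 with an estimated correlation), but passed without PbfRNAi replicate 2 (adjusted p = 0.0273; adjusted p = 0.514 with an estimated correlation) and with no filter on low values (0.017; adjusted p = 0.843 with an estimated correlation).

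Of 9 basal endosperm transfer layer markers, expressed where nutrients enter the endosperm, 3 fell and none rose in PbfRNAi, on both scales and adjusted over the list alone, and 7 fell with the replicate block. Those that fell included betl4 (27.7 ± 3.75 to 6.50 ± 2.87, adjusted p = 0.0059) and the cell wall invertase gene mn1 (9.58 ± 2.48 to 3.40 ± 1.07, adjusted p = 0.026). The call of mn1 was lost without WT replicate 2 (adjusted p = 0.095), WT replicate 3 (0.093) or PbfRNAi replicate 1 (0.092). Camera gave the markers an adjusted p = 0.000286 (adjusted p = 0.67 with an estimated correlation). In replicate 1 these markers stood apart from replicates 2 and 3 by a median of −0.47 in WT, −0.52 in o2, −1.0 in PbfRNAi and −1.61 in the double genotype.

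Ribosomal protein genes rose in 20 of 29 cases in PbfRNAi and fell in none (23 adjusted over the list alone, 11 scaled; camera adjusted p = 8.47e-06; adjusted p = 0.67 with an estimated correlation). The genes leg1 (1.85-fold), fl3 (4.48-fold), psei10 (3.68-fold, and 5.87-fold without WT replicate 1) and pho1, for starch phosphorylase (1.84-fold), rose on both scales. The ascorbate peroxidase gene apx2 fell to 0.453 of WT, in an oxidative stress list of 4 rises and 6 falls, or 2 and 7 scaled (camera adjusted p = 0.053, and 0.019 to 0.05 without any of WT replicate 1, o2 replicate 2, PbfRNAi replicates 2 or 3, or any double library; adjusted p = 0.67 with an estimated correlation). Rises and falls numbered 2 and 0 of 3 for other reserve proteins (1 and 0 scaled), 5 and 1 of 23 for starch (but 3 and 1), 4 and 2 of 14 for transcription factors (3 and 2), 5 and 0 of 18 for defence (3 and 1, but 5 and 1 adjusted over the list alone), 1 and 1 of 15 for central carbon (1 and 1) and 3 and 0 of 11 for the aspartate family (2 and 0). They numbered 3 and 0 of 4 for elongation (1 and 0 scaled, 4 and 0 adjusted over the list alone), 1 and 0 of 16 for heat shock (0 and 0, and none adjusted over the list alone), 1 and 0 of 18 for histones (0 and 0, and none adjusted over the list alone), 1 and 1 of 5 for late embryogenesis (1 and 1) and 1 and 0 of 4 for embryo markers (0 and 0). No aleurone marker was called, 1 of 2 embryo surrounding region markers fell, and the green tissue marker psah1 rose. Camera passed for heat shock proteins without PbfRNAi replicate 1 (adjusted p = 0.026; adjusted p = 0.617 with an estimated correlation) and for elongation without PbfRNAi replicate 2 (0.0439; adjusted p = 0.514 with an estimated correlation).

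Other large rises in PbfRNAi were those of xet1, a xyloglucan endotransglycosylase gene (0.423 ± 0.0650 to 14.8 ± 6.84), pep4 (23.5-fold), TCP7 (6.39-fold) and the unnamed GRMZM2G046382 (1.13 ± 0.993 to 238 ± 21.2). Large falls were those of a GTPase gene (to 0.0395 of WT), CAF1 (0.181), BURP7 (0.291) and betl-9 (0.296). The call of betl-9 was lost without WT replicate 2 (adjusted p = 0.06) or PbfRNAi replicate 1 (0.052). In total 3097 genes were higher and 881 lower, against 1934 and 1645 scaled and 1784 and 1965 scaled to genes outside the 100 most abundant. Scaled to genes that are not zeins they numbered 1739 and 1496. Calls numbered 2637 without WT replicate 2, against 3978, and 8343 genes were called without the 4 replicate 1 libraries.

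Of 20 alpha-zein models 16 fell and 1 rose in the double genotype, and of 25 zein models 19 fell and 2 rose, on both scales and adjusted over the list alone. The rises counted are again those of z1A2_1 and of gz27, whose WT values of 0 can be failed estimates. By the same split, the 10 z1C1 models that fell stood at 0.023 of WT or less, and the 6 z1A models that fell, of 9 tested, at 0.227 to 0.527 of WT. The level of z1C1_8 went from 14478 ± 4615 to 107 ± 83.9 (log2 −7.75 ± 0.91, adjusted p = 5.3e-05), that of z1C1_7 from 4602 ± 1629 to 39.3 ± 31.1 and that of z1C1_2 from 2565 ± 932 to 3.94 ± 3.23. The gamma-zein gz50 fell from 6194 ± 1024 to 229.9 ± 44.4 (log2 −4.75 ± 0.38) and bz15 to 0.396 of WT, while gz16 stood at 24282 ± 2808 and 24222 ± 3711 (adjusted p = 0.98, and 0.024 for a lower value scaled to genes outside the 100 most abundant). The alpha-zein z1A2_1 rose 8.50-fold (to 8824 ± 4387), and gz27, listed at 0 in WT, stood at 13241, 13686 and 12457. By camera, zeins had an adjusted p = 1.06e-26, alpha-zeins 3.76e-25, and the beta, gamma and delta zeins (3 falls and 1 rise of 5) 0.000138. With an estimated correlation each of the 3 had an adjusted p = 0.0195, which became 0.214 when scaled. Scaled to genes outside the 100 most abundant, the beta, gamma and delta zeins did not pass (adjusted p = 0.119).

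Most ER chaperone, ribosomal protein, histone and defence genes had higher values in the double genotype. ER chaperones rose in 17 of 22 cases (11 scaled, and 10 rose and 2 fell scaled to genes outside the 100 most abundant), with bip1 at 409.6 ± 43.8 and PDIL1-1 at 1256 ± 213 (camera adjusted p = 0.0273; adjusted p = 0.552 with an estimated correlation). That camera call was lost without PbfRNAi;o2 replicate 1 (adjusted p = 0.0754). Ribosomal protein genes rose in 28 of 29 cases (29 adjusted over the list alone, 22 scaled; camera adjusted p = 1.28e-06; adjusted p = 0.453 with an estimated correlation), and elongation genes in 4 of 4 (3 scaled). Histone and replication genes rose in 15 of 18 cases (10 scaled), histone2b1 4.12-fold (77.2 ± 12.6 to 318 ± 31.1) and his2b2 4.84-fold. By camera they had an adjusted p = 0.0914, and passed with the replicate block (0.00345) and without WT replicate 2 (0.0383), without WT replicate 3 (0.0296) and without o2 replicate 1 (0.0215). With an estimated correlation they had an adjusted p = 0.813, and 0.469 to 0.722 in those 4 settings. In replicate 1 they stood lower than in replicates 2 and 3, by a median of −0.78 in WT, −0.99 in o2, −0.62 in PbfRNAi and −0.23 in the double genotype. Defence genes rose in 15 and fell in 1 of 18 cases (10 and 2 scaled; camera adjusted p = 0.144; adjusted p = 0.67 with an estimated correlation). With median-of-ratios scaling camera passed for histone (0.00259; adjusted p = 0.564 with an estimated correlation) and defence genes (0.00661; adjusted p = 0.463 with an estimated correlation). Defence genes that rose included psei10 (8.09-fold, and 12.9-fold without WT replicate 1), psei6 (5.05-fold) and the chitinase gene chiB (3.11-fold). The gene that fell was rip1 (1749.5 ± 476 to 202 ± 171, adjusted p = 0.017, and 0.051 without WT replicate 3).

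Further rises in the double genotype on each scale tried were those of fl3 (10.6-fold, to 5541 ± 1297), leg1 (2.96-fold), the aleurone regulator nkd1 (3.06-fold), the globulin gene glb1 (10.5-fold), PDIL1-2 (16.8-fold), ZIP4 (9.42-fold) and DBP2 (5.88 ± 0.381 to 64.7 ± 4.34). Gene pdk1 fell to 0.203 of WT (523 ± 98.04 to 106 ± 12.9, adjusted p = 1e-06) and apx2 to 0.376. Starch genes were higher in 12 and lower in 2 of 23 cases, but 1 higher and 2 lower when scaled, and sh2 (1542 ± 245 to 2786 ± 300.1) did not pass when scaled (adjusted p = 0.39). Central carbon genes were higher in 9 and lower in 2 of 15 cases (5 and 3 scaled). Oxidative stress genes were higher in 5 and lower in 8 of 22 cases (1 and 10 scaled; camera adjusted p = 4.65e-06; adjusted p = 0.0737 with an estimated correlation).

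Camera also placed below other genes in the double genotype the aspartate family (3 higher and 2 lower of 11, 3 and 1 adjusted over the list alone, but 1 and 3 scaled; adjusted p = 0.029; adjusted p = 0.223 with an estimated correlation), transcription factors (5 and 3 of 14, but 3 and 5 scaled; 0.0173; adjusted p = 0.0755 with an estimated correlation) and transfer layer markers (0 and 1 of 9, 0 and 0 adjusted over the list alone; 0.0121; adjusted p = 0.568 with an estimated correlation). All 3 were lost without PbfRNAi;o2 replicate 1 (adjusted p = 0.388, 0.0591 and 0.559) and with median-of-ratios scaling (0.144, 0.0824 and 0.208). Elongation genes (adjusted p = 0.0636) passed without PbfRNAi replicate 1 (0.0282) or without PbfRNAi replicate 2 (0.0368), each lost with an estimated correlation (adjusted p = 0.325 and 0.454 with an estimated correlation). They also passed with median-of-ratios scaling (0.039), scaled to non-zein genes (0.0351), scaled to genes outside the 100 most abundant (0.0287) and with no filter on low values (0.016), but at adjusted p = 0.343 to 0.463 with an estimated correlation. Other reserve proteins were higher in 2 of 3 cases (2 scaled), heat shock proteins in 6 of 16 (5 adjusted over the list alone, 3 scaled), late embryogenesis genes in 2 of 5 (1 scaled) and embryo markers in 2 of 4 (1 higher and 1 lower scaled). Aleurone markers were higher in 2 and lower in 1 of 5 cases (2 and 2 scaled), 1 of 2 embryo surrounding region markers was lower, and the green tissue marker was not called. In total 9448 genes were higher and 811 lower, against 3374 and 2766 scaled, and the balance turned to 2337 and 4256 scaled to genes outside the 100 most abundant. Scaled to genes that are not zeins the numbers were 4190 and 1924.

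The double genotype was compared with o2 to measure the effect of PbfRNAi where O2 is lost. The largest falls among named genes included those of gz50 (5571 ± 286 to 229.9 ± 44.4; log2 −4.61 ± 0.38, adjusted p = 4.6e-06), the GTPase gene (29.7 ± 1.62 to 0.350 ± 0.119) and z1C1_4 (75.6 ± 55.1 to 5.30 ± 5.05). The largest rises included those of z1A2_1 (295 ± 134 to 8824 ± 4387), the wound-induced gene wip1 (0.515 ± 0.293 to 26.1 ± 18.1), sfp5 (12.1-fold) and the lipoxygenase gene lox12 (9.50-fold). Zeins fell in 7 and rose in 1 of 25 cases (camera adjusted p = 0.00283, but 0.0549 with scaling to genes outside the 100 most abundant and 0.077 without all 4 replicate 1 libraries), and alpha-zeins fell in 6 and rose in 1 of 20. ER chaperones rose in 7 of 22 cases and fell in none (9 and 1 adjusted over the list alone, 5 higher and 1 lower scaled; 0.0158), with bip1 2.62-fold and bip2 2.89-fold higher, and ribosomal protein genes in 7 of 29 (10 adjusted over the list alone, 3 scaled; 0.0139). Defence genes rose in 7 and fell in 1 of 18 cases (8 and 1 adjusted over the list alone, 7 and 1 scaled; 0.0176), histone genes rose in 6 of 18 (7 adjusted over the list alone, 5 scaled; 0.0158), and 1 of 9 transfer layer markers fell (0.0158). Each of these lists had an adjusted p = 0.779 with an estimated correlation. The call of defence genes was lost without PbfRNAi;o2 replicate 2 (0.0514), that of histones without o2 replicate 1 (0.124) and that of transfer layer markers without PbfRNAi;o2 replicate 1 (0.436), where the aspartate family passed (0.0395, on the higher side; adjusted p = 0.572 with an estimated correlation).

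Between o2 and the double genotype pdk1 fell further (212 ± 21.8 to 106 ± 12.9, adjusted p = 0.0013) and pho1 rose 2.04-fold. The values of rip1 were 99.8 ± 26.03 and 202 ± 171 (log2 −0.34 ± 1.33, adjusted p = 0.89), and without PbfRNAi;o2 replicate 1 its log2 change was 1.61 (adjusted p = 0.013). In total 2456 genes were higher and 1337 lower, against 2119 and 1776 scaled, and 1697 and 2403 scaled to genes outside the 100 most abundant. Scaled to genes that are not zeins, 1930 and 1752 were. Without the 4 replicate 1 libraries 8444 genes were called, against 3793, and the balance turned to 3990 higher and 4454 lower.

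The double genotype was compared with PbfRNAi to measure the effect of o2 where pbf1 is reduced. Zeins fell in 18 and rose in none of 25 cases (19 adjusted over the list alone, 19 scaled), among them z1C1_8 (9486 ± 1601 to 107 ± 83.9; log2 −7.18 ± 0.91, adjusted p = 0.00018), z1C1_2 (1711 ± 85.6 to 3.94 ± 3.23) and gz50 (1290.3 ± 766 to 229.9 ± 44.4). The delta-zein dzs18 went from 34.3 ± 13.4 to 0.580 ± 0.0510 and bz15 from 15902 ± 1455 to 7349.7 ± 662 (adjusted p = 0.017, and 0.052 without PbfRNAi replicate 2). Camera gave the zeins an adjusted p = 1.42e-23 (adjusted p = 0.0344 with an estimated correlation, 0.0871 with the replicate block as well). Gene pdk1 fell to 0.187 of its PbfRNAi level. Large rises were those of BURP6 (0.997 ± 0.452 to 101 ± 47.8), BURP9 (33.3-fold), ERTC (9.64-fold) and ZIP4 (8.42-fold).

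Histone genes rose in 13 of 18 cases between PbfRNAi and the double genotype (15 adjusted over the list alone, 7 scaled; camera adjusted p = 0.0418; adjusted p = 0.859 with an estimated correlation), histone2b1 2.53-fold. That call was lost without PbfRNAi replicate 1 (adjusted p = 0.205), without PbfRNAi;o2 replicate 2 (0.087) or without PbfRNAi;o2 replicate 3 (0.115). Ribosomal protein genes rose in 23 and fell in 1 of 29 cases (9 and 1 scaled; camera adjusted p = 0.00246; adjusted p = 0.826 with an estimated correlation). Heat shock proteins rose in 4 of 16 cases on both scales (camera adjusted p = 0.598, and 0.0266 with the replicate block; adjusted p = 0.612 with an estimated correlation as well). Aspartate family genes fell in 4 of 11 cases (2 adjusted over the list alone, 4 scaled; 0.00246; adjusted p = 0.0787 with an estimated correlation), a camera call lost without PbfRNAi;o2 replicate 1 (0.0527), where transfer layer markers passed (0.0233, with 2 of 9 higher; adjusted p = 0.696 with an estimated correlation). Oxidative stress genes (6 higher and 5 lower of 22, 7 and 5 adjusted over the list alone, but 1 and 7 scaled; adjusted p = 0.0154; adjusted p = 0.368 with an estimated correlation) and transcription factors (3 and 3 of 14, and 1 and 4 scaled; 0.0186; adjusted p = 0.0787 with an estimated correlation) lay below other genes. The first of these did not pass with median-of-ratios scaling (0.135). Elongation genes passed without PbfRNAi replicate 1 (0.0446, against 0.239; adjusted p = 0.447 with an estimated correlation). In total 6633 genes were higher and 1024 lower, against 2586 and 2208 scaled, and 1749 and 3088 scaled to genes outside the 100 most abundant. Scaled to genes that are not zeins there were 3525 and 1540.

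The interaction tests whether the double genotype departs from the sum of the single effects. That of pbf1 was −1.13 ± 0.21 (adjusted p = 0.0056), with a higher level in o2 (293 ± 45.9) than in the double genotype (59.5 ± 4.97). Interactions below 0 were also called for gz50 (−2.15 ± 0.54, adjusted p = 0.028), pdk1 (−1.11 ± 0.24, adjusted p = 0.013) and psei10 (−2.43 ± 0.50, adjusted p = 0.011). The call of gz50 was lost without WT replicate 1 (0.053) or 3 (0.069), o2 replicate 2 (0.066) or 3 (0.064), PbfRNAi replicate 3 (0.062) or double replicate 3 (0.06). In total 1590 genes were called, 654 above and 936 below the sum (891 and 765 scaled, which turns the balance). Calls numbered 2513 with the replicate block, 1055 without o2 replicate 3 and 7621 without the 4 replicate 1 libraries, the last with 1811 above and 5810 below. Scaled to genes outside the 100 most abundant, 790 were above and 845 below, and scaled to genes that are not zeins 809 and 700. Of the zeins 3 were above and 3 below of 25 (3 and 4 adjusted over the list alone), those above being z1C1_1, z1C1_11 and z1C1_12, which o2 alone took near the lowest value the log2 scale can show. No list passed camera (smallest adjusted p = 0.0551, for histones, and 0.00147 with the block, where it was 0.982 with an estimated correlation). Leaving out single libraries gave camera calls for histones (0.00081 to 0.014 without any of WT replicate 1, o2 replicates 2 or 3, PbfRNAi replicates 2 or 3, or double replicate 1), for defence genes (0.0499 without PbfRNAi replicate 2, 0.0337 without PbfRNAi replicate 3, 0.00852 without PbfRNAi;o2 replicate 1), for ribosomal proteins (0.00144 without PbfRNAi replicate 2) and for transfer layer markers (0.0139 without PbfRNAi;o2 replicate 1). With an estimated correlation each of these lists had an adjusted p = 0.999, and 0.958 to 0.998 in those leave-outs.

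The effect of each lesion was also compared between backgrounds, in contrasts that share no library. Across 17058 genes the log2 effects of o2 with and without PbfRNAi correlated at r = 0.456, and those of PbfRNAi with and without o2 at r = 0.464. Of 5117 genes called for o2 in both backgrounds 95.3% had the same direction, as had 91.3% of 1649 for PbfRNAi. Independent calls of these directions would give 82.9% and 58.2%. With median-of-ratios scaling the shares were 89.3% of 1461, against 50.2%, and 89.7% of 1608, against 50.4%. Among named genes, z1C1_8 fell and BURP6 and ZIP4 rose with o2 in both backgrounds, while gz50 and the GTPase gene fell and z1A2_1 and bip1 rose with PbfRNAi in both.

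**Figure D4:**
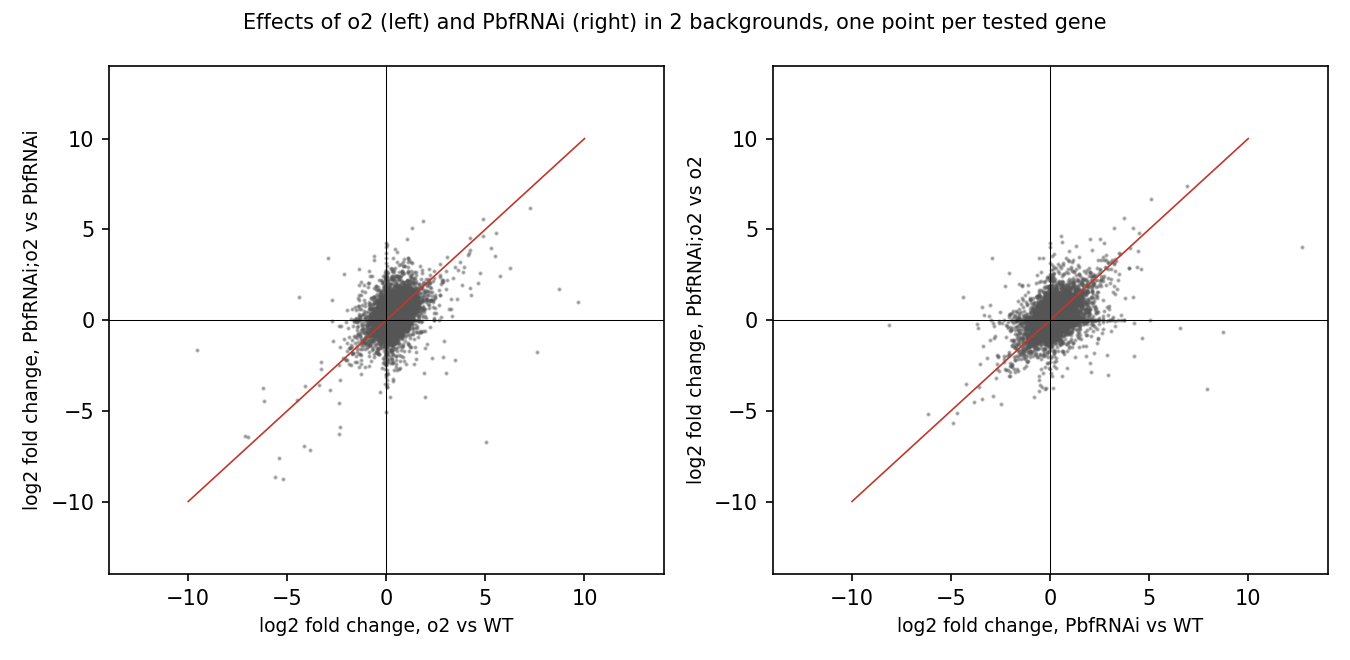
Log2 fold changes of the 17058 tested genes for o2 (left) and PbfRNAi (right), with the effect in the intact background on the x axis and in the background of the other lesion on the y axis. Each point is a gene, the line marks equal effects, and the correlations across genes are 0.456 and 0.464.

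Calls against WT in the single genotypes overlapped. The genes fl3, leg1 and psei10 rose and z1C1_12 fell in both. In all, 1805 genes were higher in both and 89 lower in both, where independent lists of these sizes would share 1503.7 and 23.1, and 397 were called in opposite directions, against 509.1. With median-of-ratios scaling 345 were higher in both, 306 lower in both and 232 opposite, against 171.2, 130.7 and 299.2 for independent lists. Scaled to genes outside the 100 most abundant, these numbers were 261, 446 and 228, against 117.6, 209.7 and 319.8, and scaled to genes that are not zeins 421, 199 and 237, against 260.1, 79.1 and 315.7. Both comparisons use the same 3 WT libraries, which are too few to split, so part of the excess may come from the shared controls. Unchanged groups simulated against those libraries gave 0 genes called in both. They were drawn without any effect, so this 0 cannot show how much the shared controls add among changed genes. The correlation of effects across genes was 0.215 and their covariance 0.0666, against 0.506 and 0.0237 for the simulated groups. Without the 4 replicate 1 libraries the shared calls numbered 5331 in place of 1894. They numbered 1003 without WT replicate 2, and without WT replicate 3 1049.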

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

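The difference in effect between backgrounds was tested by the interaction for each gene below, and the limma test, fixed in advance, is what singled these results out. Of the tests of explanations in this part, the zein share and the other list medians in replicate 1, the amount of mRNA and the assignments within replicate numbers were chosen after the result was seen, and the rescaling to genes outside the 100 most abundant was added after the first results. In all, 1590 genes had an interaction of o2 and PbfRNAi. As many calls came up in 1 of 100 assignments of the residuals over all libraries, the real one included, and the highest of the others gave 1442. Within replicate numbers it was again 1 of 100, and the highest of the others gave 0. The share of 0.01, the smallest these draws can give, argues against chance in the assignment for the count as a whole but does not exclude it. Residuals of the additive model still hold any interaction, so the draws mix it into the spread and lean toward few calls.

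The alpha-zein z1C1_12 had an interaction of 7.86 (adjusted p = 3.9e-07), with 1927 ± 793 in WT, 1.52 ± 0.893 in o2, 5.48 ± 0.196 in PbfRNAi and 1.04 ± 0.213 in the double genotype. The interaction of z1C1_11 was 2.50, with 61.2, 93.00 and 87.3 in the WT libraries, 0, 0 and 0.181 in o2, 8.84, 13.3 and 16.8 in PbfRNAi and 0, 0.0430 and 0 in the double genotype. In both genes o2 alone left values near 0, the floor of log2(FPKM + 1), so the sum of the 2 single falls cannot be reached and an interaction above 0 follows from the scale. That of z1C1_4 was −3.53 (adjusted p = 0.031) and was lost with the replicate block (0.056) and, at 0.056 to 0.072, without any 1 of the WT or PbfRNAi libraries, o2 replicate 2 or double replicate 3. That of z1C1_2 was −3.06 (adjusted p = 0.036) and was lost with the block (0.069), with median-of-ratios scaling (0.053) and, at 0.06 to 0.082, without any 1 of the WT or PbfRNAi libraries, o2 replicate 3 or double replicate 3.

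The interaction of sfp5 was 2.49 (adjusted p = 0.00061), with means of 8.68 in WT, 2.52 in o2, 14.01 in PbfRNAi and 30.4 in the double genotype. That of lox12 was 2.19 (adjusted p = 0.00027), with 1.84, 1.52, 2.87 and 14.4 in the same order, and that of chiA 2.44, with 8.43, 10.6 and 11.3 in the double libraries and at most 2.10 elsewhere. That of TCP7 was −3.63 (adjusted p = 5.5e-05), with 2.79, 9.35, 17.8 and 3.42. That of tps10 was −3.67 and that of ris2 −3.71, with 20.3, 13.3 and 12.1 and 15.97, 10.1 and 10.9 in the PbfRNAi libraries, and the double libraries stood at 0 for tps10 and 0, 0.0440 and 0 for ris2. That of pbf1 was −1.13 (adjusted p = 0.0056).

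For the counts of calls, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes. The real and the highest other count were 8730 and 0 for o2 against WT, 3978 and 1 for PbfRNAi against WT, 10259 and 1 for the double genotype against WT, 3793 and 8 for the double genotype against o2, and 7657 and 2 for it against PbfRNAi.

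Most genes called in o2 against WT were higher, 94.9% on the FPKM scale. When each library was rescaled to its genes outside the 100 most abundant, 38.2% of the calls were higher, and median-of-ratios scaling gave 52.7%. Such rescaling centres most genes whatever moved them, so the bound of 60% written in advance decides nothing. The 10 most abundant genes did take less of the FPKM sum, 21.4% to 28.0% in o2 against 39.0% to 41.5% in WT. All other genes together thus took more of it. How much of the rises on the FPKM scale follows from this share stays open. More mRNA per cell of most genes in o2 stays open too, because FPKM holds no amount of mRNA and 94.9% says nothing on it.

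A set of 81 genes stood near 0 in 1 genotype and was abundant in another, such as GRMZM2G092758, listed at 0 in each WT and o2 library and at 30.9, 37.3 and 30.8 in PbfRNAi. Of these genes 42% were at exactly 0 in all 3 libraries of the lowest genotype, between the 20% and 50% written as bounds, so failed estimates listed at exactly 0 stay open. Differences in linked chromosome segments between the lines stay open too. There were 2 pairs within 5 tested genes of each other, under the bound of 3 from 10000 random draws (mean 0.7), but not by more than the counting spread, and 41 of the 81 genes could be placed, a reading set after the value was seen. Calls did cluster in gene order, with 13 of 50 neighbouring genes lower in PbfRNAi against WT in 1 window (adjusted p = 5.4e-05), and an effect of the factors themselves on these genes was not tested apart from the lines.

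Replicate 1 stood apart from replicates 2 and 3 in every genotype, with heat shock protein genes higher. In some genes chosen after the values were seen, double replicate 1 lay nearer to WT and o2, and replicates 2 and 3 to PbfRNAi. The double libraries stood at 61.5, 0.406 and 0.148 for PDIL5-1 (GRMZM2G443655). They stood at 19.1, 0.047 and 0.077 for GRMZM2G031572 and at 0, 10.9 and 10.6 for ohp1. Other genes that PbfRNAi changed did not split so, such as the GTPase gene (0.478, 0.331 and 0.243). The cause of the split was not tested, and double means pool these libraries. Embryo tissue in the replicate 1 samples is argued against, since the embryo markers had medians of −0.05, −0.30, −0.71 and −0.43 in WT, o2, PbfRNAi and the double genotype, and in PbfRNAi the highest of the 4 stood at −0.60. A heat or similar stress response stays open: the heat shock proteins, singled out among 19 lists and 4 genotypes, go with it, and 10 heat shock factor genes had medians of 0.17, −0.16, −0.21 and 0.19, which met the bound of 0.1 written against it in advance, but their values ran from −0.69 to 2.42 in PbfRNAi, so the median decides nothing, a reading set after the value was seen. Another endosperm stage stays open: the share of zeins higher in replicate 1 was 36%, 68%, 32% and 12%, a range of 56, and the zein median, the first statistic, differed in sign between genotypes (−0.44, 0.76, −0.18 and −1.50) and was replaced after it was seen, while 6 lists had medians below 0 in every genotype: histones (−0.78, −0.99, −0.62 and −0.23), starch (−0.27, −0.57, −0.44 and −0.33), transfer layer, embryo, late embryogenesis and defence genes. No biological explanation from the design was tested, as the labels do not say what the number marks.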

How the results depend on the processing

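Scaling to genes outside the 100 most abundant, median-of-ratios scaling with the block, leaving out all 4 replicate 1 libraries and leaving out 4 zein models listed at 0 were chosen after the results were seen. Of 192 calls on named genes (218 results in all), those lost and gained were 2 and 0 with a pseudocount of 0.1, 1 and 1 with a pseudocount of 5, 6 and 0 with no filter, 0 and 0 with a filter at FPKM 5 and 0 and 0 with no variance trend. They were 14 and 5 with median-of-ratios scaling, 10 and 3 with scaling to non-zein genes, 17 and 6 with scaling outside the 100 most abundant, 5 and 3 with the replicate block, 12 and 6 with both scaling and block, 20 and 6 over the leave-outs of 1 library, 1 and 12 without all 4 replicate 1 libraries, 0 and 0 without the 4 zein models and 13 and 0 when a 2-fold change was required. In the fit of only the genotypes compared, 5 of 173 were lost and 2 gained. Of 36 list calls in 114 tests, 1, 0, 5 and 5 were lost with pseudocounts of 0.1 and 5, no filter and the filter at FPKM 5, 8, 6 and 13 with the 3 scalings in the order above, 1 with the block, 10 with scaling and block, 10 over the leave-outs, 7 without the 4 replicate 1 libraries, and 0 with no variance trend or without the 4 zein models. Those gained were 0, 2, 6, 1, 3, 3, 6, 3, 7, 14, 11, 0 and 0. Beyond those in the report, the list calls lost included those for endosperm transcription factors in all 3 comparisons that called them and for the aspartate family and transfer layer markers in the double genotype (no filter), for elongation in o2, ER chaperones in the double genotype, defence genes in it against o2 and oxidative stress genes and histones in it against PbfRNAi (filter at FPKM 5, and histones also with a pseudocount of 0.1). Scaling outside the 100 most abundant also ended those of transfer layer markers against o2 and of transcription factors and beta, gamma and delta zeins against PbfRNAi. Calls gained included those of ER chaperones in o2 (no filter), late embryogenesis genes in o2 and histones in the interaction (pseudocount 5), oxidative stress genes in PbfRNAi (filter), and, with scaling outside the 100 most abundant, other reserve proteins in o2 and defence genes and heat shock proteins in the double genotype against PbfRNAi. Lists were not run with only the genotypes compared or with a required 2-fold change.

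With the replicate block the calls rose from 8730 to 10290 for o2, 3978 to 5289 for PbfRNAi and 10259 to 11360 for the double genotype against WT. They rose from 3793 to 5180 for the double genotype against o2, from 7657 to 9248 against PbfRNAi and from 1590 to 2513 for the interaction. Beside the calls named in the report and the interactions of z1C1_4 and z1C1_2, the block changed those of wx1 (gained in o2 and the double genotype against WT), agp2 (gained in o2), lkrsdh1 (lost in the double genotype against WT and against PbfRNAi) and bip2 (lost in the interaction), and no other call on lists or on a gene that the report names for that comparison. Over the 755 results that the rule for named genes gives, 378 of them called, it lost 7 and gained 66. The 74 list calls gained over all settings, each left-out library being 1, had an adjusted p of at least 0.188 with an estimated correlation.

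Median-of-ratios scaling gave 2865 calls for o2, 6140 for the double genotype, 4794 for it against PbfRNAi and 651 shared by the single genotypes. The values were 3453, 6114, 5065 and 620 with scaling to non-zein genes and 2944, 6593, 4837 and 707 with scaling outside the 100 most abundant. Scaling with the block gave 4606 for o2, 2786 for the interaction and 1249 shared. A filter at FPKM 5, which tests fewer genes, gave 2345 for the double genotype against o2 and 948 for the interaction. A required 2-fold change, a stricter rule by construction, gave 1314, 1155 and 3004 for o2, PbfRNAi and the double genotype against WT, 1251 and 1651 for the double genotype against o2 and PbfRNAi, 934 for the interaction and 150 shared. The correlation of o2 effects was 0.354 with a pseudocount of 0.1 and 0.561 with 5. Without all 4 replicate 1 libraries, calls numbered 8343 for PbfRNAi, 8444 for the double genotype against o2, 7621 for the interaction and 5331 shared.

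Over the leave-outs of 1 library, calls ranged from 6508 to 9466 for o2, 2637 to 4640 for PbfRNAi, 8711 to 10560 for the double genotype, 2656 to 4232 for it against o2, 5861 to 8065 against PbfRNAi and 1055 to 2179 for the interaction, and shared calls from 1003 to 2290. The correlations ranged from 0.408 to 0.469 for o2 and 0.431 to 0.472 for PbfRNAi. The change of rip1 between o2 and the double genotype ranged from −1.35 to 1.61 and was 1.81 without all 4 replicate 1 libraries. Heat shock proteins turned to the higher side of other genes by camera in o2 without those libraries (median 0.979) and in the double genotype with scaling and block (median 0.747). Except for the filter and the 2-fold rule, the cause was not tested. The depth of the libraries is unknown, so what it limits cannot be given.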

Other observations

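The position windows and the groups of genes near 0 described here were chosen after the first results were seen. Some unnamed models were nearly specific to lines. GRMZM2G092758 was listed at 0 in each WT and o2 library, and at 30.9, 37.3 and 30.8 in PbfRNAi and 85.7, 111 and 105 in the double libraries. GRMZM2G437040 stood at 28.6, 50.3 and 36.6 in WT and 34.2, 60.3 and 59.2 in o2, at 0, 0.653 and 0.247 in PbfRNAi and at 0 in each double library. GRMZM2G404688 stood at 0.230, 0 and 0.220 in WT, 578, 468 and 397 in o2, 68.6, 111 and 159.7 in PbfRNAi and 431, 344 and 299 in the double genotype. GRMZM2G021973 stood at 36.1, 14.8 and 14.9 in WT, was listed at 0 in each o2 and PbfRNAi library and stood at 0.569, 1.31 and 2.91 in the double genotype. Among the 81 genes near 0 in 1 genotype and abundant in another, 7 were at 10 or more in PbfRNAi and the double genotype and low in WT and o2, 4 the reverse, 3 were low in o2 and the double genotype alone (the o2 gene itself and the alpha-zeins z1C1_1 and z1C1_11) and 2 were at 10 or more in these alone.

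In some comparisons and directions called genes clustered along the gene order of the reference, in which 12062 tested genes were placed in 235 windows of 50. No window passed for genes higher in o2 against WT, in the double genotype against WT or in it against PbfRNAi. The smallest hypergeometric adjusted p was 0.3, 0.17 and 0.27 in that order. Windows past the threshold numbered 2 for genes lower in o2, 10 and 7 for genes higher and lower in PbfRNAi, 2 for genes lower in the double genotype against WT, 4 and 2 for genes higher and lower against o2, and 5 for genes lower against PbfRNAi. For the interaction they numbered 4 above and 9 below, the densest with 16 of 50 genes (adjusted p = 5.4e-09). In the window of the o2 gene itself 9 genes were lower in o2 (adjusted p = 8e-04), while 7 lower in the double genotype against WT (adjusted p = 0.11) and 8 lower in it against PbfRNAi (adjusted p = 0.17) did not pass.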
